A study of Homo sapiens with 12 samples.

How the data were processed

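Messenger RNA of human pancreatic adenocarcinoma cells was sequenced in 12 libraries, 3 in each of 4 groups. The cells belong to the line the labels call MIA, an abbreviation they do not spell out, and to PANC1, an established pancreatic carcinoma line. Per the labels' protocols, the cells grew in DMEM with fetal bovine serum and antibiotics. A small interfering RNA (siRNA) was given at 20 nM in reduced-serum medium for 6 h, and the cells were harvested 48 h after transfection. The control arm received a Silencer Select siRNA whose target the labels do not name, and the other arm 1 Silencer Select siRNA against TCF7L1. Total RNA was made into libraries with a KAPA kit that selects messenger RNA and marks strand. Groups were read from the sample titles and the siRNA entries. The letters LC in the PANC1 titles are not explained in the labels. Nothing in the labels says that the 3 libraries of a group came from separate cultures, so p-values measure only the spread between these libraries, which may be technical.

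Each library has a gene table in the RSEM format. Per the submitters' processing notes, Bowtie2 2.29, RSEM 1.2.25, edgeR and the hg19 build were used, with no role or order given. The deposited expected counts are the reads that RSEM assigned to each gene, and they need not be whole because reads that match several genes are split by estimation. The TPM column deposited by the authors gives transcript abundance as RSEM scaled it to an equal total in each library, and it served in 2 alternative fits. The FPKM column deposited by the authors, fragments scaled to gene length and library total, and the deposited gene lengths were read and checked for range but entered no test. Each table holds 25343 gene symbols built from RefSeq transcripts, per the transcript identifiers in the tables. The strand setting of the counting, the read length, the filters and any pooling of runs are not given in the sources used here. Reads of a gene and of its antisense or overlapping partner therefore cannot be told apart, and genes with near-identical copies are uncertain. The tables hold 0 symbols with the MT- prefix, so the list of mitochondrially encoded genes, 13 symbols, could not be measured.

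Expected counts summed to between 16309191 and 21380311 per library. In units of 1e6 counts they averaged 18.9 ± 2.54 in control MIA (SD, n = 3), 19.9 ± 0.69 in siTCF7L1 MIA, 19.9 ± 1.06 in control PANC1 and 18.0 ± 1.55 in siTCF7L1 PANC1. Replicate pairs were compared with a chi-square test over genes with at least 20 counts. The statistic per degree of freedom lay between 3.56 and 9.36, no pair held identical values, and all 12 libraries were kept as separate samples.

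For the tests, expected counts were rounded to whole numbers. Library sizes were scaled with TMM factors and weakly counted genes were removed with filterByExpr. Each gene was tested with edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3), with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05 on the adjusted p. The siTCF7L1 and control arms were compared within the 6 libraries of each line. The difference between the lines' responses was the interaction contrast over all 12 libraries, PANC1 effect minus MIA effect, and the control libraries of the lines were compared with each other in a separate fit. Standard errors of log2 fold changes were computed as the absolute log2 fold change divided by the square root of the F statistic. Levels are counts scaled to a TMM-adjusted library size of 1e6 (CPM), as mean ± SD over 3 libraries. The lines share no control library, and the calls shared by both lines were set against the product of the 2 call counts divided by the genes tested in both.

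Before the data were examined, 32 gene lists were written down for pathways, complexes and markers of other cell types, together with the tests, the alternatives and the rule for the genes to be named. The rule named TCF7L1 and the other TCF/LEF genes. For each line it took the 12 genes with the largest rise and the 12 with the largest fall among those past the threshold, with a mean of at least 5 CPM and with no overlap between the arms. For both lines it took the 10 genes each way with the largest smaller fold change, for the difference the 6 each way at 5 CPM or more, and for the control lines the 6 each way at 20 CPM or more. For a described list it took the 4 members with the smallest p, some of which are not reported here. Pseudogenes, ribosomal RNA, features with no symbol and genes that reveal sex were left out. Lists with at least 5 measured members were tested with camera in limma 3.58.1 on log2 CPM (prior count 2), two-sided, with the preset inter-gene correlation of 0.01 and Benjamini-Hochberg adjustment over the 31 lists of a comparison. Camera with an estimated correlation and the rotation test fry were alternatives. Beside the count of members past the threshold over all genes stands the count adjusted over the list alone.

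Symbols were matched to a RefSeq gene table on GRCh38 for current symbols, gene types and chromosomes. There 22442 matched directly, 2544 through a transcript identifier and 214 through an older symbol, and 143 had no match. GENCODE release 29 on GRCh38, joined by the given or current symbol, was used for gene positions and transcript sequences. The counts rest on hg19. To look for siRNA seed effects, log2 fold changes of the genes tested in a line were regressed on the presence of each 7-base sequence. Presence was scored in the longest annotated 3′ untranslated region (UTR). The covariates were UTR length and its square, GC content and its square, and log2 mean CPM. UTRs of at least 50 bases and sequences found in at least 20 genes were used. A UTR was found for 88.9% of the genes tested in MIA and 89.6% of those tested in PANC1. The sequences AAAAGGA, GACAGTA and GACGTA, the last common to several sequences with strong rises, were chosen from this scan, so their shares among falls and rises are descriptive. After the data had been seen, shorter forms of the sequences were also searched in the longest protein-coding transcript of each gene. Other regulatory sites, and the sequences of the siRNAs, were not analysed here.

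The code was tested on simulated counts with 200 changed genes, drawn with the means and the trended spread of the real libraries. For MIA, run on 13777 genes, 62% of genes changed by 0.5 on the log2 scale and 86% of those changed by 1 were recovered, with 13 false calls. For PANC1, run on 14661 genes, the shares were 70% and 89% with 8 false calls. For the interaction, run on 15429 genes, they were 54% and 73% with 5 false calls, and for the control lines, run on 14805 genes, 61% and 85% with 7. A gene list shifted by 0.3 was recovered in each line, on 13936 and 14839 genes, and 0 of the 30 other lists were called. The simulated genes were drawn independently of each other, so false list calls that arise from correlated genes were not tested. Far fewer genes were changed than passed the test in the data, so the recovered shares need not hold there. A planted 7-base sequence ranked 1 in each simulated scan.

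The alternatives were RLE and upper quartile size factors, no filter and a stricter filter on low counts, counts without rounding, and a replicate block. DESeq2 1.42.0, limma-voom, and limma on log2(TPM + 1) and log2(TPM + 0.1) replaced the test. A fit of all 12 libraries together, a 2-fold threshold and leaving out each library in turn completed the set. Removal of genes with the 3′ UTR sites was added after the data had been seen. Tables and figures were made with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Intervals and floors cover counting error only, since the reads carry no molecular identifiers that the sources used here mention.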

Results

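TCF7L1, a transcription factor of the TCF/LEF family that mostly represses Wnt target genes, fell in both pancreatic cancer lines 48 h after transfection of its siRNA. In MIA its level went from 30.5 ± 4.31 to 3.79 ± 0.331 CPM (mean ± SD, n = 3 libraries per group), 8.01 times lower, and in PANC1 from 9.15 ± 1.03 to 2.80 ± 0.165 CPM, 3.26 times lower. The log2 fold changes were −3.002 ± 0.12 (SE) in MIA and −1.71 ± 0.14 in PANC1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 1.84e-09 and 1.70e-06). The libraries held 508, 565 and 631 TCF7L1 counts in control MIA and 74, 81 and 71 after the siRNA, against 162, 170 and 221 in control PANC1 and 46, 57 and 47 after it.

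The other family members did not pass the test. TCF7, the TCF family's T cell factor 1, had a log2 fold change of 0.02 ± 0.05 in MIA (293 ± 10.5 to 298 ± 14.4 CPM) and −0.09 ± 0.09 in PANC1 (16.5 ± 1.31 to 15.4 ± 0.284 CPM). For TCF7L2, the main TCF of many epithelia, the values were 0.19 ± 0.09 in MIA (17.3 ± 1.97 to 19.6 ± 1.23 CPM) and −0.03 ± 0.07 in PANC1 (33.7 ± 2.11 to 33.1 ± 1.66 CPM). The adjusted p of the edgeR quasi-likelihood test (Benjamini-Hochberg) was 0.758 and 0.444 for TCF7, and 0.129 and 0.803 for TCF7L2. LEF1 was too weakly counted for a test in MIA, with 7 reads over the control group and 4 after the siRNA, and had a value of −0.37 ± 0.26 in PANC1 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.275).

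**Figure D1:**
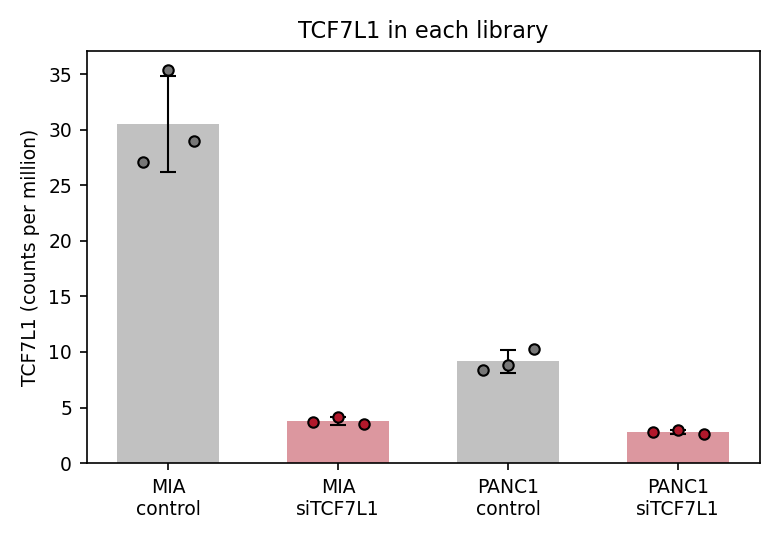
TCF7L1 level in CPM (vertical axis) in control and siTCF7L1 libraries of MIA and PANC1 (horizontal axis). Bars stand for means, error bars for the SD and points for the 3 libraries of each group; in MIA the means were 30.5 and 3.79, and in PANC1 9.15 and 2.80.

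In MIA, the largest rises after the siRNA among genes with a mean of at least 5 CPM and no overlap between the arms were in PTGES, which makes prostaglandin E2, and CDA, the cytidine deaminase that inactivates gemcitabine. PTGES rose 3.48-fold, from 55.8 ± 1.31 to 194 ± 2.79 CPM, and CDA from 3.14 ± 0.339 to 9.61 ± 0.526 CPM (log2 fold change ± SE, 1.80 ± 0.05 and 1.61 ± 0.13). The CDK inhibitor p21 gene CDKN1A rose by 1.46 ± 0.10, from 4.89 ± 0.105 to 13.5 ± 0.344 CPM, the cyclin D3 gene CCND3 by 1.40 ± 0.06, from 20.5 ± 0.569 to 54.1 ± 1.88 CPM, and the transcription factor E2F2 by 1.38 ± 0.14. The largest falls among such genes, besides TCF7L1, were in LIN9, a subunit of the MuvB complex that controls cell cycle genes, at −2.11 ± 0.08 (from 55.1 ± 4.17 to 12.7 ± 0.771 CPM), and in the transcriptional corepressor ATN1, at −2.09 ± 0.06 (from 249.5 ± 18.0 to 58.4 ± 1.72 CPM). By the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 1.76e-10 for PTGES, 6.63e-07 for CDA, 2.36e-07 for CDKN1A, 5.58e-10 for LIN9 and 1.76e-10 for ATN1.

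Among the other 7 genes chosen for their rises in MIA were ZCCHC3 at 1.54 ± 0.07, the lysosomal amino acid transporter SLC36A1 at 1.42 ± 0.10 and the costimulatory receptor TNFRSF9 (4-1BB) at 1.40 ± 0.11. AVPI1 rose by 1.30 ± 0.07 and the long noncoding RNA LOC54944 by 1.54 ± 0.09. The rises of the translation factor subunit EIF3C, 1.35 ± 0.27, and of the DNA repair nuclease ERCC5, 1.28 ± 0.16, are uncertain, because EIF3C has a near-identical copy and ERCC5 overlaps a readthrough gene. Their adjusted p, the largest of this set, was 0.00150 and 3.74e-05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Falls covered the chaperonin subunit CCT7 (−2.08 ± 0.06, from 582 ± 38.8 to 138 ± 6.60 CPM), the cytoskeletal linker PLEC (−1.82 ± 0.06), the interleukin-1 receptor family member SIGIRR (−1.92 ± 0.17) and the growth factor FGF1 (−1.78 ± 0.17). The RNA-binding protein gene HNRNPA0 fell by 1.91 ± 0.07, the prothymosin gene PTMA by 1.91 ± 0.08, the paraoxonase PON2 by 1.84 ± 0.06, the homeobox gene HOXC8 by 1.84 ± 0.12 and the mitotic kinase NEK9 by 1.71 ± 0.09. The 3′ UTRs of E2F2, CCND3, SLC36A1, HNRNPA0, PTMA, PON2, HOXC8 and NEK9 carry the sequence AAAAGGA.

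In total 5526 of 13936 tested genes changed in MIA (39.7%), 2712 up and 2814 down, and 328 of them changed at least 2-fold (136 up and 192 down). Most changes were small, with a median absolute log2 fold change of 0.36 among the changed genes. For 49.98% of the tested genes the 2 arms did not overlap, where chance gives 10%. Libraries of the 2 arms lay apart on the first principal component, which held 51.4% of the variance.

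4 of the 31 lists tested moved in MIA, and 0 of them hold with an estimated correlation. Sterol and fatty acid synthesis genes moved up, with a median of 0.31 (camera adjusted p = 5.98e-06, adjusted p = 0.798 with an estimated correlation). Of 31 measured members, 22 rose, 1 fell and 8 did not pass the test (22 and 2 adjusted over the list alone). The fatty acid enzymes FASN 0.89 ± 0.05 and ACACA 0.86 ± 0.06, their regulator SREBF1 0.92 ± 0.06 and the lanosterol synthase LSS 0.61 ± 0.05 had the smallest p. Genes of G2/M and mitosis moved down, with a median of −0.16 (camera adjusted p = 3.21e-04, adjusted p = 0.798 with an estimated correlation). Of 45 measured members, 1 rose, 23 fell and 21 did not pass the test (2 and 26 adjusted over the list alone). Examples are the kinetochore gene CENPF −0.78 ± 0.05, the kinesins KIF4A −0.59 ± 0.06 and KIF14 −0.41 ± 0.05 and the topoisomerase TOP2A −0.44 ± 0.06.

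Cytosolic ribosomal protein genes moved up in MIA, with a median of 0.13 (camera adjusted p = 0.00976, adjusted p = 0.811 with an estimated correlation). Of 49 measured members, 18 rose, 2 fell and 29 did not pass the test (18 and 2 adjusted over the list alone), with RPS15 0.36, RPS19 0.29 and RPL18 0.28 up and RPL14 −0.57 down. Nuclear genes of oxidative phosphorylation did the same, with a median of 0.13 (camera adjusted p = 0.0132, adjusted p = 0.798 with an estimated correlation). Of 44 measured members, 20 rose, 3 fell and 21 did not pass the test (22 and 4 adjusted over the list alone), with SDHD 0.43, SDHA 0.34 and ATP5A1 0.34 up and cytochrome c, CYCS, −0.44 down. Both calls are lost without MIA control library 3 (adjusted p = 0.194 and 0.113) or siTCF7L1 library 3 (0.0666 and 0.0677). The MTRNR2L genes, near-copies of the mitochondrial 16S ribosomal RNA that were chosen after their values were seen, took 1.34 ± 0.11% of counts in control MIA and 1.82 ± 0.02% after the siRNA (mean ± SD, n = 3). In PANC1 their share was 0.43 ± 0.06% and 0.66 ± 0.07%.

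In PANC1, the water and glycerol channel AQP3 rose most among genes chosen in the same way, from 2.22 ± 0.283 to 8.55 ± 1.70 CPM (log2 fold change 1.93 ± 0.18), followed by CYP1A1, a target of the aryl hydrocarbon receptor, from 4.74 ± 0.210 to 15.7 ± 1.01 CPM (1.73 ± 0.11). The receptor tyrosine kinase gene MET rose 2.83-fold, from 55.4 ± 5.83 to 157 ± 4.74 CPM (1.502 ± 0.07). LIN9 fell most among them, 4.39-fold, from 30.8 ± 1.35 to 7.06 ± 1.73 CPM (−2.13 ± 0.13), and the thymidylate synthase gene TYMS fell from 101 ± 1.59 to 30.7 ± 0.418 CPM (−1.72 ± 0.06). HMGA2, a chromatin protein of embryonic and tumor cells, fell from 141 ± 9.49 to 44.8 ± 4.87 CPM (−1.66 ± 0.08). In the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 3.24e-06 for AQP3, 2.01e-07 for CYP1A1, 2.99e-08 for MET, 1.46e-07 for LIN9, 4.42e-09 for TYMS and 3.04e-08 for HMGA2.

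Other strong rises in PANC1 were the arginine deiminase PADI3 (1.69 ± 0.10), the ammonium transporter RHCG (1.59 ± 0.14) and the chemokine CX3CL1 (1.48 ± 0.10). The adaptor subunit AP1S3 rose by 1.51 ± 0.06 and the cargo receptor subunit MCFD2 by 1.502 ± 0.06. SLC36A1 rose by 1.47 ± 0.13, as did ANKRD52, a subunit of protein phosphatase 6, by 1.46 ± 0.09. TSPEAR-AS1 (1.62 ± 0.17) is an antisense gene whose reads cannot be told from those of its partner; its adjusted p of 8.17e-06 is the largest of this set (edgeR quasi-likelihood test, Benjamini-Hochberg). Falls included the microtubule protein MAP1B (−1.73 ± 0.08, from 201 ± 16.6 to 60.6 ± 4.11 CPM), the glycosyltransferase GALNT1 (−1.70 ± 0.08), the protocadherin PCDH9 (−1.55 ± 0.10) and ATN1 (−1.53 ± 0.09). HOXC8 fell by 1.70 ± 0.10, the RNA-binding La protein SSB by 1.63 ± 0.06, the ribosome biogenesis gene EBNA1BP2 by 1.62 ± 0.08 and PPCS, an enzyme of coenzyme A synthesis, by 1.56 ± 0.07. The 3′ UTRs of MAP1B, TYMS, GALNT1, HOXC8, HMGA2, SSB, EBNA1BP2, PPCS, PCDH9, AP1S3, MCFD2 and SLC36A1 carry AAAAGGA, and reads of TYMS cannot be told from those of its antisense neighbour ENOSF1.

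Of 14839 genes tested in PANC1, 5815 changed (39.2%), 2978 up and 2837 down, and 372 changed at least 2-fold (168 up and 204 down). The median absolute log2 fold change of the changed genes was 0.42. The arms did not overlap for 49.5% of the tested genes, where chance gives 10%. The first principal component held 52.0% of the variance and set the arms apart.

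9 lists moved in PANC1, and 1 of them, G2/M and mitosis genes, holds with an estimated correlation. Its median was −0.44 (camera adjusted p = 1.34e-13, adjusted p = 0.0220 with an estimated correlation). Of 45 measured members, 0 rose, 40 fell and 5 did not pass the test (0 and 40 adjusted over the list alone). The mitotic kinesins KIF4A −0.90 ± 0.07 and KIF20A −0.90 ± 0.07, the spindle protein DLGAP5 −0.73 ± 0.06 and the kinase AURKA −0.72 ± 0.06 fell. G1/S and DNA replication genes moved down too, with a median of −0.22 (camera adjusted p = 8.45e-05, adjusted p = 0.737 with an estimated correlation). Of 43 measured members, 2 rose, 24 fell and 17 did not pass the test (2 and 25 adjusted over the list alone). Besides TYMS, the falls included 2 other genes of nucleotide and DNA synthesis, RRM2 −0.86 ± 0.06 and PRIM1 −0.92 ± 0.08. In MIA the G1/S list had a median of 0.03 and did not move (camera adjusted p = 0.591). There 13 rose, 7 fell and 23 did not pass the test (13 and 7 adjusted over the list alone), the helicase subunit MCM2 at 0.41 and TYMS at −1.53 among them.

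Metabolic genes moved up in PANC1. Sterol and fatty acid synthesis genes had a median of 0.39 (camera adjusted p = 7.06e-05, adjusted p = 0.751 with an estimated correlation). Of 32 measured members, 20 rose, 0 fell and 12 did not pass the test (20 and 0 adjusted over the list alone), led by the enzymes ACACA 0.78, LSS 0.77, FADS2 0.67 and ACLY 0.53. Hypoxia and glycolysis genes had a median of 0.18 (camera adjusted p = 0.00438, adjusted p = 0.791 with an estimated correlation). Of 35 measured members, 17 rose, 1 fell and 17 did not pass the test (17 and 1 adjusted over the list alone), with the glucose transporter SLC2A3 1.25 and the glycolytic enzymes GPI 0.63, HK2 0.59 and PFKL 0.41. For oxidative phosphorylation genes the median was 0.10 (camera adjusted p = 0.0414, adjusted p = 0.791 with an estimated correlation). Of 44 measured members, 14 rose, 3 fell and 27 did not pass the test (14 and 3 adjusted over the list alone), with SDHA 0.50, SDHD 0.38 and NDUFV1 0.35 up and CYCS −0.56 down. This last call is lost without PANC1 control library 3 (adjusted p = 0.306), siTCF7L1 library 1 (0.0622) or siTCF7L1 library 3 (0.120).

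Lysosome and autophagy genes moved up in PANC1, with a median of 0.21 (camera adjusted p = 0.00150, adjusted p = 0.622 with an estimated correlation). Of 30 measured members, 17 rose, 4 fell and 9 did not pass the test (19 and 4 adjusted over the list alone), with the hydrolase NEU1 0.73 up and the autophagy gene ATG12 −0.66 down. Integrin and extracellular matrix genes did as well, with a median of 0.21 (camera adjusted p = 0.00414, adjusted p = 0.553 with an estimated correlation). Of 36 measured members, 17 rose, 4 fell and 15 did not pass the test (18 and 4 adjusted over the list alone). The integrin ITGA3 rose by 0.57, the syndecan SDC4 by 0.57 and the laminin LAMB1 by 0.52.

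Small RNA pathway genes moved down in PANC1, with a median of −0.24 (camera adjusted p = 0.0189, adjusted p = 0.751 with an estimated correlation). Of 13 measured members, 0 rose, 7 fell and 6 did not pass the test (1 and 8 adjusted over the list alone). The Argonaute gene AGO4 −0.96, its partner TNRC6A −0.61 and the nuclease DICER1 −0.62 fell and carry AAAAGGA, and PRKRA −0.48 fell and does not. Immediate early and MAPK feedback genes followed, with a median of −0.20 (camera adjusted p = 0.0309, adjusted p = 0.690 with an estimated correlation). Of 31 measured members, 4 rose, 11 fell and 16 did not pass the test (4 and 12 adjusted over the list alone), with the AP-1 genes FOSL1 −0.82 and JUN −0.61 and the ERK phosphatase DUSP6 −0.997 down. Without siTCF7L1 library 1 of PANC1 both calls are lost (adjusted p = 0.0622 and 0.0697), and the second also without siTCF7L1 library 3 (0.0828). Leaving out genes with the 3′ UTR sites, an alternative chosen after seeing the data, ends both as well (adjusted p = 0.347 and 0.164), with medians of −0.24 and −0.20 over the 5 and 21 members left. AGO4, TNRC6A and DICER1 are among those left out, and in MIA the same step took the small RNA median from −0.23 to −0.02.

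Several lists moved in one line and did not pass in the other. In MIA, lysosomal cathepsin genes went both ways, CTSD 0.53 and CTSL −0.77: of 30 lysosome and autophagy genes 11 rose, 4 fell and 15 did not pass (11 and 4 adjusted over the list alone), with a median of 0.11 and a camera adjusted p = 0.253. The urokinase receptor PLAUR −0.57 and LAMB1 −0.55 fell, and of 32 integrin and matrix genes 4 rose, 13 fell and 15 did not pass (5 and 13 adjusted over the list alone), with a median of −0.12 and a camera adjusted p = 0.253. SLC2A3 1.01 and the stress gene DDIT4 0.62 rose, and of 33 hypoxia and glycolysis genes 11 rose, 5 fell and 17 did not pass (13 and 5 adjusted over the list alone), with a median of 0.16 and a camera adjusted p = 0.125. AGO4 −0.61 and AGO3 −0.43 fell, and of 13 small RNA pathway genes 1 rose, 6 fell and 6 did not pass (1 and 7 adjusted over the list alone), with a median of −0.23 and a camera adjusted p = 0.289. JUN −0.58 and DUSP6 −1.10 fell, and of 32 immediate early genes 6 rose, 12 fell and 14 did not pass (6 and 14 adjusted over the list alone), with a median of −0.07 and a camera adjusted p = 0.289. In PANC1, RPL14 −0.57 fell and RPS15 0.21 rose, and of 49 ribosomal protein genes 4 rose, 1 fell and 44 did not pass (0 and 1 adjusted over the list alone), with a median of 0.02 and a camera adjusted p = 0.609.

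**Figure D2:**
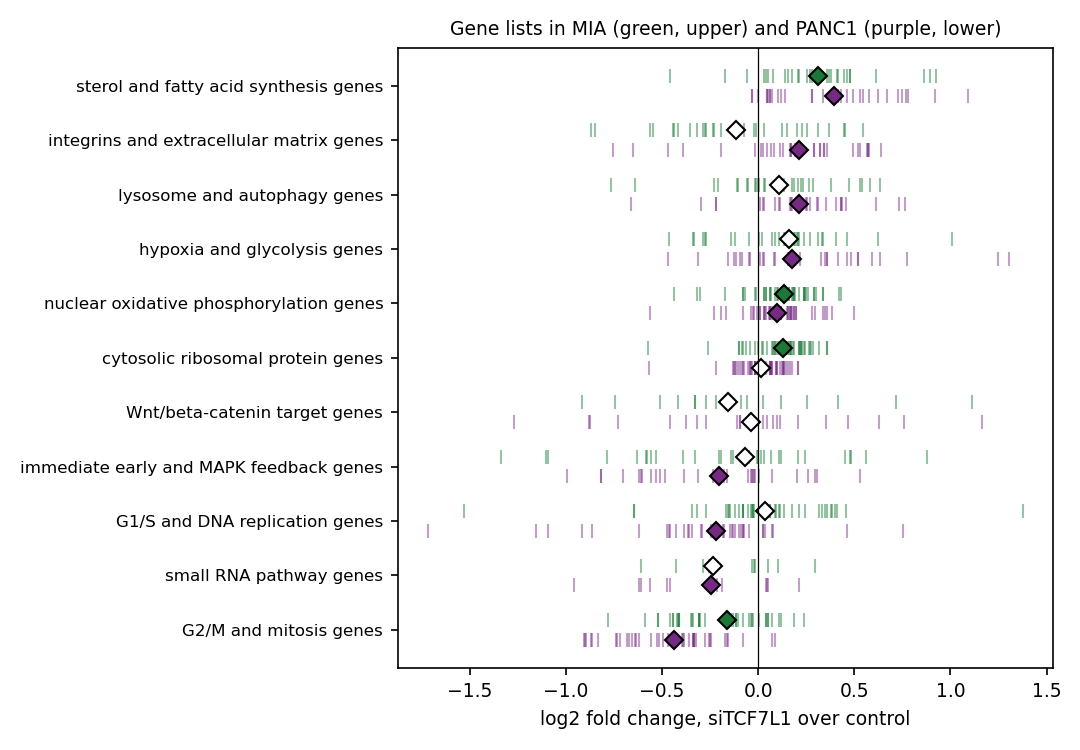
Log2 fold change, siTCF7L1 against control (horizontal axis), of the measured members of 11 gene lists (vertical axis). Ticks stand for genes and diamonds for list medians, MIA above and PANC1 below in each pair; a filled diamond marks a camera adjusted p below 0.05, as for the G2/M and mitosis genes with medians of −0.16 and −0.44.

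Wnt/beta-catenin target genes did not move as a list in either line. In MIA the inhibitor of differentiation gene ID2 1.11 ± 0.08 and the Notch ligand JAG1 0.72 ± 0.06 rose, and the cyclin D1 gene CCND1 −0.92 ± 0.06 and the Wnt antagonist DKK1 −0.51 ± 0.05 fell. In PANC1 CCND1 −0.88 ± 0.06 fell, and JAG1 0.76 ± 0.07, WISP2 1.17 ± 0.10 and the Wnt deacylase NOTUM 0.63 ± 0.11 rose. Of 18 Wnt targets measured in MIA, 3 rose, 5 fell and 10 did not pass (3 and 6 adjusted over the list alone), with a median of −0.16 and a camera adjusted p = 0.436. PANC1 had 23 measured, of which 4 rose, 5 fell and 14 did not pass (4 and 5 adjusted over the list alone), with a median of −0.04 and a camera adjusted p = 0.870. In the TCF/LEF family and beta-catenin complex, PYGO2 rose in both lines (0.56 and 0.58), the corepressor TLE3 rose in MIA (0.30) and fell in PANC1 (−0.42), and the kinase HIPK2 fell in both (−0.56 and −0.86). In MIA, of 14 genes of this complex 4 rose, 2 fell and 8 did not pass (4 and 2 adjusted over the list alone), with a median of 0.01 and a camera adjusted p = 0.834. Among 16 in PANC1, 3 rose, 3 fell and 10 did not pass (3 and 3 adjusted over the list alone), with a median of −0.01 and a camera adjusted p = 0.796. TCF7L1, the target of the siRNA, is itself a member of this list and is counted among its falls in both lines. The mean of this list in MIA, −0.17, differed in sign from its median and from the direction of camera's test. That mean includes TCF7L1, by far the largest fall of the list in MIA, with HIPK2 at −0.56 the next. A single large value weighs more on a mean than on a median.

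Among Wnt ligands, receptors and inhibitors, the receptor FZD8 0.52 rose in MIA, FZD6 fell in both lines (−0.62 and −0.69), and the Wnt acyltransferase PORCN 0.86 and DKK3 0.56 rose in PANC1. The 25 such genes of MIA did not move: 4 rose, 6 fell and 15 did not pass (4 and 6 adjusted over the list alone), with a median of −0.07 and a camera adjusted p = 0.506. Nor did the 32 of PANC1, where 12 rose, 4 fell and 16 did not pass (12 and 4 adjusted over the list alone), with a median of 0.11 and a camera adjusted p = 0.112. Of the pluripotency and stem cell regulators, the aldehyde dehydrogenases ALDH1A1 (−1.55 and −0.90) and ALDH1A3 (−1.06 and −0.65) fell in both lines, and the let-7 inhibitor LIN28B −1.39 and SOX2 −0.82, which were not tested in MIA, fell in PANC1. Of 10 regulators measured in MIA, 1 rose, 6 fell and 3 did not pass (1 and 6 adjusted over the list alone), with a median of −0.31 and a camera adjusted p = 0.0837. PANC1 had 15 measured, of which 3 rose, 7 fell and 5 did not pass (3 and 7 adjusted over the list alone), with a median of −0.36 and a camera adjusted p = 0.136. ALDH1A1, ALDH1A3 and SOX2 carry AAAAGGA in the 3′ UTR, and LIN28B does not. Without genes that carry the sites, the PANC1 median of this list turned to 0.15 over 7 members (camera adjusted p = 0.852). In the Notch and Hedgehog pathways, the target gene HES4 0.96 rose and NOTCH3 −0.67 fell in MIA, the effector GLI2 fell in both lines (−1.44 and −0.50), and the ligand DLL4 0.73 rose in PANC1. In MIA, of 23 pathway genes 6 rose, 5 fell and 12 did not pass (7 and 5 adjusted over the list alone), with a median of 0.01 and a camera adjusted p = 0.833. Among 25 in PANC1, 6 rose, 3 fell and 16 did not pass (6 and 3 adjusted over the list alone), with a median of 0.12 and a camera adjusted p = 0.230.

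Epithelial and mesenchymal genes gave mixed values. The tight junction gene CLDN1 rose in both lines (0.95 in MIA and 1.21 in PANC1), KRT19 fell in MIA (−0.40) and the splicing regulator ESRP2 fell in PANC1 (−0.55). The 11 epithelial genes of MIA did not move: 4 rose, 3 fell and 4 did not pass (5 and 3 adjusted over the list alone), with a median of 0.16 and a camera adjusted p = 0.506. Nor did the 23 of PANC1, where 10 rose, 4 fell and 9 did not pass (10 and 4 adjusted over the list alone), with a median of 0.25 and a camera adjusted p = 0.0830. The intermediate filament gene VIM fell in both lines (−0.80 and −0.62) and S100A4 rose in both (0.68 and 0.73), and the repressor ZEB1 fell in both (−0.60 and −0.51). Of 16 mesenchymal genes measured in MIA, 2 rose, 7 fell and 7 did not pass (2 and 7 adjusted over the list alone), with a median of −0.11 and a camera adjusted p = 0.360. PANC1 had 25 measured, of which 10 rose, 6 fell and 9 did not pass (10 and 6 adjusted over the list alone), with a median of 0.09 and a camera adjusted p = 0.545. Of the TGF-beta response genes, the corepressor TGIF1 fell (−0.78 and −0.64) and SKI rose (0.65 and 0.48) in both lines. In MIA, of 21 TGF-beta response genes 6 rose, 6 fell and 9 did not pass (7 and 6 adjusted over the list alone), with a median of 0.11 and a camera adjusted p = 0.360. Among 23 in PANC1, 4 rose, 8 fell and 11 did not pass (4 and 8 adjusted over the list alone), with a median of −0.11 and a camera adjusted p = 0.327. Of the YAP/TAZ targets, AXL (−0.58 and −0.37) and NT5E (−0.58 and −0.49) fell and ARHGEF17 (0.51 and 0.75) rose in both lines. The 20 targets of MIA did not move: 7 rose, 5 fell and 8 did not pass (8 and 5 adjusted over the list alone), with a median of 0.07 and a camera adjusted p = 0.506. Nor did the 23 of PANC1, where 9 rose, 7 fell and 7 did not pass (9 and 7 adjusted over the list alone), with a median of 0.09 and a camera adjusted p = 0.491.

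Markers of other cell types did not move as lists with the siRNA. PAX6 fell in both lines (−0.40 and −0.53), KRT19 in MIA and FOXA2 (−0.53) in PANC1. Of 8 acinar, ductal and endocrine genes measured in MIA, 1 rose, 2 fell and 5 did not pass (2 and 3 adjusted over the list alone), with a median of −0.15 and a camera adjusted p = 0.862. PANC1 had 13 measured, of which 0 rose, 2 fell and 11 did not pass (0 and 1 adjusted over the list alone), with a median of −0.09 and a camera adjusted p = 0.566. The smooth muscle actin ACTA2 rose in MIA (0.90), and COL1A2 fell in both lines (−0.40 and −0.33). In MIA, of 6 fibroblast and stellate markers 2 rose, 2 fell and 2 did not pass (2 and 2 adjusted over the list alone), with a median of 0.06 and a camera adjusted p = 0.862. Among 8 in PANC1, 2 rose, 1 fell and 5 did not pass (2 and 1 adjusted over the list alone), with a median of 0.07 and a camera adjusted p = 0.870. The mean of 0.04 in PANC1 was positive and camera's direction down. CORO1A rose in both lines (0.62 and 0.74) and CD68 fell in MIA (−0.49). The 6 leukocyte markers of MIA did not move: 2 rose, 2 fell and 2 did not pass (3 and 2 adjusted over the list alone), with a median of 0.22 and a camera adjusted p = 0.724. Nor did the 6 of PANC1, where 1 rose, 0 fell and 5 did not pass (1 and 0 adjusted over the list alone), with a median of 0.13 and a camera adjusted p = 0.4998. ROBO4 fell (−1.20) and CDH5 rose (1.69) in MIA, and KDR fell (−0.52) in PANC1. Of 5 endothelial markers measured in MIA, 1 rose, 1 fell and 3 did not pass (1 and 1 adjusted over the list alone), with a median of −0.11 and a camera adjusted p = 0.643. PANC1 had 5 measured, of which 0 rose, 1 fell and 4 did not pass (0 and 1 adjusted over the list alone), with a median of −0.26 and a camera adjusted p = 0.392. The mean of 0.04 in MIA was positive and the median and camera's direction negative.

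Many genes changed the same way in both lines. Rises shared by MIA and PANC1 included SLC36A1 with log2 fold changes of 1.42 and 1.47, the mitochondrial phosphatase PTPMT1 (1.25 and 1.44), CDA (1.61 and 1.11), PTGES (1.80 and 1.083) and the glucose transporter SLC2A3 (1.01 and 1.25). ANKRD52 (1.04 and 1.46), IFFO2 (1.02 and 1.25), the aldehyde dehydrogenase ALDH3B1 (1.01 and 1.18), ERCC5 (1.28 and 1.14) and the mitochondrial import receptor TOMM20 (1.02 and 1.003) rose as well. Besides TCF7L1, the falls shared by the lines were led by LIN9 (−2.11 and −2.13), HOXC8 (−1.84 and −1.70), SSB (−1.54 and −1.63), ATN1 (−2.09 and −1.53) and TYMS (−1.53 and −1.72). EBNA1BP2 (−1.49 and −1.62), PON2 (−1.84 and −1.44), the E3 ligase gene RNF11 (−1.61 and −1.43) and PPCS (−1.42 and −1.56) completed the named falls. The largest adjusted p among these 20 genes was 0.00183, for ERCC5 in PANC1 (edgeR quasi-likelihood test, Benjamini-Hochberg).

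Of 13276 genes tested in both lines, 1450 rose in both and 1573 fell in both, 3023 in all. The near balance of rises and falls depends on the unit: with log2(TPM + 1), 999 rose and 1572 fell in both lines, 1908 rose and 2874 fell in MIA and 2269 rose and 2761 fell in PANC1. The product of the call counts, 2653 and 2720 rises and 2733 and 2638 falls, gives 543.6 shared rises and 543.1 shared falls for independent lists, so the observed counts were 2.67 and 2.90 times as high. Calls pointed in opposite directions for 161 genes, against 1087 for independent lists, and 94.9% of the genes called in both lines went the same way. Across genes, the log2 fold changes of the lines correlated with r = 0.54 and rho = 0.55 (r = 0.54 without TCF7L1), where genes are not independent replicates. At least 2-fold, 21 genes rose and 53 fell in both lines, and 1 gene, the pseudogene PTENP1, named here after its values were seen, went opposite ways. Of the 9 named shared falls other than TCF7L1, 7 carry AAAAGGA in the 3′ UTR and 2, LIN9 and ATN1, do not. Of the 10 named shared rises, SLC36A1, PTPMT1, ALDH3B1 and TOMM20 carry it too. List members named for falls in both lines also differ. Those that carry it include AGO4, ALDH1A1, ALDH1A3, AXL, CYCS, DDX21, GLI2, HIPK2, KIF4A, MDM2, NPM1, PAX6, PMAIP1, RPL14 and SAMD9. CCND1, DUSP6, FZD6, JUN, NT5E, VIM and ZEB1 are among those that do not. Among genes with a 3′ UTR, the sequence, which was chosen from these fold changes, was in 46.6% of the 1510 shared falls against 25.3% of the genes tested in both lines. Of the named shared rises, SLC36A1, PTPMT1, ERCC5, SLC2A3 and TOMM20 carry GACAGTA or GACGTA, chosen in the same way, which were in 20.9% of the 1408 shared rises against 12.6% of genes. The lines share no control libraries.

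**Figure D3:**
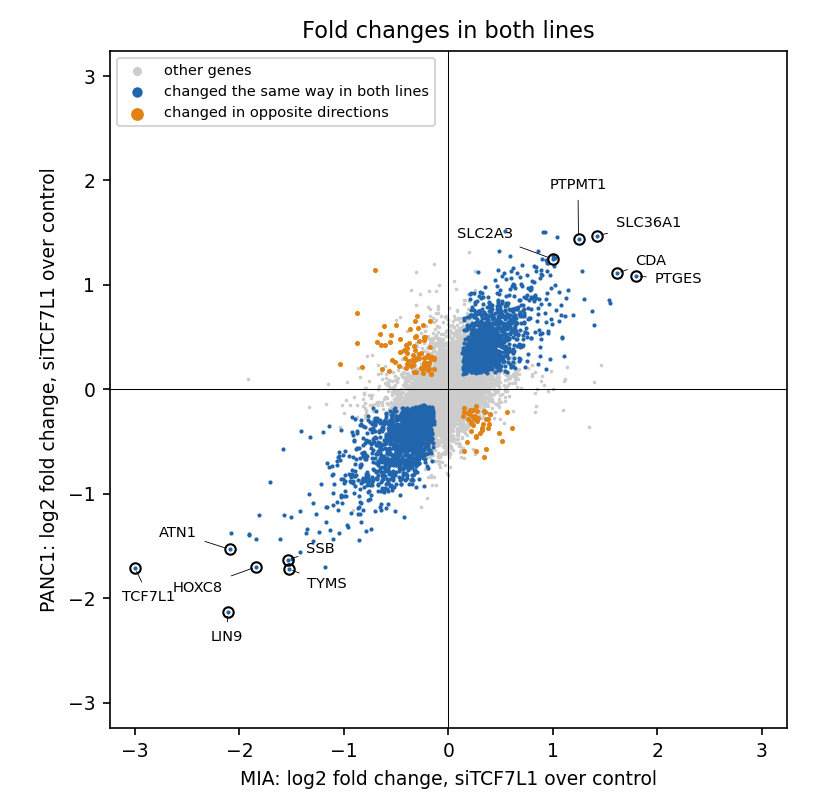
Log2 fold change, siTCF7L1 against control, in MIA (horizontal axis) and PANC1 (vertical axis) of the 9894 genes with a mean of at least 5 CPM in each line. Points stand for genes, blue where the calls go the same way, orange where they go opposite ways and grey otherwise, and circled genes are named; r was 0.54 across all genes tested in both lines.

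The response differed between the lines for 1775 of 15591 tested genes (11.4%), with 929 higher and 846 lower in PANC1 than in MIA. TCF7L1 itself fell less in PANC1, with a difference of 1.28 ± 0.20 on the log2 scale (PANC1 effect minus MIA effect). SIGIRR, an inhibitor of interleukin-1 receptor signals, fell in MIA (−1.92) and had a value of 0.10 in PANC1, a difference of 2.00 ± 0.19. TNS4, a focal adhesion protein, fell in MIA (−0.89) and rose in PANC1 (1.081), a difference of 1.95 ± 0.36, while the sushi domain gene SUSD5 rose in MIA (1.62) and fell in PANC1 (−0.50), a difference of −2.14 ± 0.29. The adjusted p of these differences was 5.29e-04, 9.66e-06, 0.00197 and 1.57e-04 (edgeR quasi-likelihood test, Benjamini-Hochberg). In MIA, TNS4 and SUSD5 rest on few reads summed over 3 libraries, 89 to 51 and 21 to 69. The fall of TNS4 in MIA is lost without MIA control library 2, siTCF7L1 library 1 or siTCF7L1 library 3 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.0749, 0.0610 and 0.0596). With DESeq2 it is lost as well (Wald test, adjusted p = 0.0769), and the rise of SUSD5 in MIA has no adjusted p there. For TCF7, TCF7L2 and LEF1 the differences of −0.14, −0.23 and 0.42 did not pass (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.411, 0.235 and 0.812).

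The other 9 genes chosen for their differences, with at least 5 CPM, were too weakly counted in MIA for a test there, so their differences rest on few reads summed over 3 libraries. Differences were positive for the transporter SLC35F3 (2.70 ± 0.67, 12 to 3 reads in MIA and 616 to 937 in PANC1), PADI3 (2.42 ± 0.54, 13 to 8 reads in MIA and 325 to 932 in PANC1), LRRC15 (2.18 ± 0.47, 41 to 11 reads in MIA and 532 to 565 in PANC1) and KANK1 (2.02 ± 0.46, 23 to 8 reads in MIA and 653 to 806 in PANC1). They were negative for the ubiquitin ligase MARCH4 (−2.93 ± 0.70, 2 to 16 reads in MIA and 1427 to 1097 in PANC1), TBC1D8B (−2.80 ± 0.88, 1 to 11 reads in MIA and 3288 to 3341 in PANC1), the protease inhibitor TFPI2 (−2.37 ± 0.64, 7 to 22 reads in MIA and 4052 to 2019 in PANC1), HMGA2 (−1.93 ± 0.50, 15 to 19 reads in MIA and 8501 to 2384 in PANC1) and MAP1B (−1.75 ± 0.48, 17 to 18 reads in MIA and 12137 to 3247 in PANC1). For the lowest 3, the ratio of siTCF7L1 to control reads in MIA was 0.237 for SLC35F3 (95% exact counting interval 0.0429 to 0.879), 7.59 for MARCH4 (1.78 to 68.0) and 10.4 for TBC1D8B (1.52 to 449). The adjusted p of the differences was 0.0140, 0.00714, 0.00550 and 0.00831 for the positive genes (edgeR quasi-likelihood test, Benjamini-Hochberg). For MARCH4, TBC1D8B, TFPI2, HMGA2 and MAP1B it was 0.0104, 0.0474, 0.0228, 0.0174 and 0.0254 (edgeR quasi-likelihood test, Benjamini-Hochberg). Leaving out a MIA library ends several of these calls, with the adjusted p of the edgeR quasi-likelihood test (Benjamini-Hochberg) as follows. SLC35F3 is lost without control library 3 (0.0784) or siTCF7L1 library 1 (0.0658), KANK1 without siTCF7L1 library 3 (0.0508), and TFPI2 without control library 1 (0.0729), siTCF7L1 library 1 (0.0823) or 3 (0.103). HMGA2 is lost without control library 3 (0.0511), siTCF7L1 library 2 (0.0881) or 3 (0.0668), and MAP1B without control library 1 (0.0554) or 3 (0.0737) or siTCF7L1 library 1 (0.128) or 2 (0.0688). TBC1D8B is lost without MIA control library 1 (0.143) or 2 (0.123), MIA siTCF7L1 library 1 (0.207) or 2 (0.0975), PANC1 control library 1 (0.0689), 2 (0.0624) or 3 (0.0553), or PANC1 siTCF7L1 library 1 (0.0651), 2 (0.0544) or 3 (0.0560).

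3 lists differed between the lines' responses, and 0 hold with an estimated correlation. G1/S and DNA replication genes were lower in the PANC1 response, with a median difference of −0.31 (camera adjusted p = 1.92e-11, adjusted p = 0.295 with an estimated correlation). Of 43, 0 were higher, 20 lower and 23 did not pass the test (0 and 30 adjusted over the list alone). The licensing factor CDT1 −0.77 ± 0.10, the thymidine kinase TK1 −0.61 ± 0.08, RRM2 −0.54 ± 0.07 and MCM7 −0.51 ± 0.08 had the smallest p. G2/M and mitosis genes were lower as well, with a median of −0.33 (camera adjusted p = 3.67e-11, adjusted p = 0.210 with an estimated correlation). Of 45, 0 were higher, 22 lower and 23 did not pass the test (0 and 32 adjusted over the list alone), among them the kinesin KIF20A −0.57 ± 0.09, the kinase AURKB −0.60 ± 0.10 and the centromere protein CENPA −0.54 ± 0.09. Integrin and matrix genes were higher, with a median of 0.31 (camera adjusted p = 9.29e-07, adjusted p = 0.210 with an estimated correlation). Of 38, 15 were higher, 1 lower and 22 did not pass the test (15 and 2 adjusted over the list alone), with the laminin LAMB1 1.05 ± 0.11, ITGB4 0.56 ± 0.11, SDC4 0.40 ± 0.08 and CD44 0.36 ± 0.07.

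For the 28 other lists the camera adjusted p of the difference lay between 0.0557 and 0.951. The median, mean and test of the difference vary in sign for the pluripotency, stress response, inflammatory, Notch, pancreatic, fibroblast and leukocyte lists. Of the 1775 genes, 1738 were tested in each line, where 905 had estimates of opposite sign and 533 the same sign with the larger change in PANC1. Only 161 of the 1775 passed the test in both lines with opposite signs. The balance of 929 higher and 846 lower genes depends on scaling, test and filter: it was 1135 and 628 with RLE factors, 1185 and 588 with DESeq2 and 1127 and 679 with no filter, and it turned to 943 and 1040 with a stricter filter.

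Control PANC1 and control MIA are far apart in their basal programs. MAP9, a microtubule-associated gene, and CD69, a lymphocyte activation marker, had 0 reads over the control MIA libraries and 3052 and 2813 in control PANC1, at least 983-fold and 911-fold more when set against 3 reads over the group. The epithelial adhesion gene EPCAM (2 against 3020 reads), the transcription factors TFAP2C (1 against 2507) and HOXC10 (3 against 4507), and TBC1D8B (1 against 3288) were nearly absent from MIA. The PANC1 to MIA ratios, with 95% exact counting intervals, were 1430.0 (395.5 to 11814) for EPCAM, 2374 (426 to 93814) for TFAP2C, 1423 (487 to 6902) for HOXC10 and 3114 (558 to 123030.0) for TBC1D8B. Among the genes lower in PANC1 were the collagen COL10A1 −8.72 ± 0.19, the proteoglycan VCAN −6.83 ± 0.17, the guidance receptor ROBO4 −6.51 ± 0.13, calretinin, CALB2, −6.34 ± 0.12, the reticulon RTN1 −6.19 ± 0.09 and LAPTM5 −5.97 ± 0.10. Their adjusted p ranged from 1.94e-16 for RTN1 to 1.88e-14 for VCAN (edgeR quasi-likelihood test, Benjamini-Hochberg).

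TCF/LEF genes differed between the control lines: TCF7L1 (−1.68 ± 0.11) and TCF7 (−4.11 ± 0.08) were lower in PANC1, and TCF7L2 (1.01 ± 0.09) and LEF1 (3.56 ± 0.48) higher. The adjusted p was 1.94e-09, 7.82e-16, 5.27e-08 and 6.42e-06 in that order (edgeR quasi-likelihood test, Benjamini-Hochberg). Of 15076 tested genes 12070 differed (80.1%), 6323 higher and 5747 lower in PANC1, and 5725 by at least 2-fold (3433 and 2292). For 80.9% of genes the 2 lines did not overlap, where chance gives 10%. Line and any batch of preparation cannot be told apart in this comparison.

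8 lists differed between the control lines, and 0 hold with an estimated correlation. Epithelial genes were higher in PANC1, with a median of 4.50 (camera adjusted p = 4.19e-06, adjusted p = 0.134 with an estimated correlation). Of 23, 22 were higher, 1 lower and 0 did not pass the test (22 and 1 adjusted over the list alone). The splicing regulators ESRP1 8.12 ± 0.16 (8 reads in control MIA) and ESRP2 7.33 ± 0.16 and the junction gene LSR 4.50 ± 0.09 led, and KRT19 −0.85 ± 0.07, named after its value was seen, was the lower one. Mesenchymal genes were higher too, with a median of 2.91 (camera adjusted p = 0.0122, adjusted p = 0.708 with an estimated correlation). Of 24, 18 were higher, 5 lower and 1 did not pass the test (18 and 5 adjusted over the list alone). The matrix genes COL1A1 7.78 ± 0.12, MMP2 9.09 ± 0.16 and TGFBI 5.54 ± 0.09 were higher and COL1A2 −4.93 ± 0.08 lower, as were ZEB1 −2.80 ± 0.08 and VIM −1.40 ± 0.07, which were named after their values were seen. Setting the 3 epithelial and 4 mesenchymal members with at most 3 reads to their bound left these medians at 4.50 and 2.91. Members that stay on the same side of a median do not move it, so this is a weak check.

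TGF-beta response genes had a median of 0.82 (camera adjusted p = 0.0104, adjusted p = 0.396 with an estimated correlation). Of 23, 18 were higher, 2 lower and 3 did not pass the test (18 and 2 adjusted over the list alone), with the receptor TGFBR2 8.59 and the ligand TGFB2 4.78. YAP/TAZ targets had one of 0.81 (camera adjusted p = 0.00596, adjusted p = 0.708 with an estimated correlation). Of 23, 17 were higher, 3 lower and 3 did not pass the test (17 and 3 adjusted over the list alone), with CTGF 8.38, CRIM1 2.90 and WWC1 3.11. Unfolded protein and stress response genes reached 1.14 (camera adjusted p = 5.79e-04, adjusted p = 0.708 with an estimated correlation). Of 31, 25 were higher, 3 lower and 3 did not pass the test (25 and 3 adjusted over the list alone), led by STC2 9.71, DDIT3 3.24 and SLC7A5 2.29. Hypoxia and glycolysis genes stood at 0.74 (camera adjusted p = 0.0326, adjusted p = 0.940 with an estimated correlation). Of 35, 25 were higher, 8 lower and 2 did not pass the test (25 and 8 adjusted over the list alone), with BNIP3 8.54, ADM 7.95 and ANGPTL4 4.07.

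Cell cycle genes were lower in control PANC1. G2/M and mitosis genes had a median of −0.44 (camera adjusted p = 0.00432, adjusted p = 0.774 with an estimated correlation). Of 45, 9 were higher, 31 lower and 5 did not pass the test (9 and 31 adjusted over the list alone), with the transcription factor FOXM1 −1.68, ASPM −1.68 and UBE2C −1.24. G1/S genes had one of −0.45 (camera adjusted p = 0.0404, adjusted p = 0.940 with an estimated correlation). Of 43, 12 were higher, 24 lower and 7 did not pass the test (12 and 25 adjusted over the list alone), with GINS4 −3.49, POLA1 −2.60 and TYMS −1.28. This call is lost with log2(TPM + 1) (adjusted p = 0.0505) and with a replicate block (0.0624). For the 23 other lists the camera adjusted p lay between 0.113 and 0.955. Their median, mean and test vary in sign for the interferon, immediate early, ribosomal protein, apoptosis, leukocyte and small RNA lists.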

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

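No test in this part was chosen after its result was seen. The test of the difference between the lines' responses to the siRNA picked out 1775 genes, among them TCF7L1 at 1.28 (PANC1 effect minus MIA effect, log2). Of the named genes, the differences were SLC35F3 2.70, PADI3 2.42, LRRC15 2.18, KANK1 2.02, SIGIRR 2.00 and TNS4 1.95 on the positive side. On the negative side they were MARCH4 −2.93, TBC1D8B −2.80, TFPI2 −2.37, SUSD5 −2.14, HMGA2 −1.93 and MAP1B −1.75. Camera picked out the G1/S and DNA replication genes with a median difference of −0.31, the G2/M and mitosis genes with −0.33 and the integrin and matrix genes with 0.31, but 0 of these 3 calls hold with an estimated correlation (adjusted p = 0.295, 0.210 and 0.210).

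Among 100 splits of the arms within the lines, the real one included, 6 gave at least 1775 differing genes, so this share does not exclude chance. The 5 others exchanged all 3 libraries of each PANC1 arm, with the real arms in MIA (6855 genes) or with 1 library per arm exchanged there (1885, 1971, 2305 and 2437). Exchanging the arms of PANC1 turns the difference into the sum of the lines' effects, so these counts point to a structure of the samples. The 78 splits that mixed the arms in both lines gave at most 0 genes.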

How the results depend on the processing

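Of the alternatives, the removal of genes with the 3′ UTR sites was chosen only after the data were seen. TCF7L1 stayed past the threshold in every alternative run, between −3.08 and −2.59 in MIA, −1.77 and −1.32 in PANC1 and 1.16 and 1.40 for the difference. With another normalization, filter, unit, test, rounding or block, or all 12 libraries in 1 fit, the changed genes numbered 4649 to 5610 in MIA and 4994 to 6086 in PANC1. Both lines then shared 2562 to 3106, the difference held 1255 to 1983 and the control lines 10228 to 13116. DESeq2 called 4587 of the 5526 MIA genes, 5078 of the 5815 PANC1 genes and 1487 of the 1775 differing genes in the same direction. Leaving out each library gave 4425 to 5487 genes in MIA, 4485 to 5414 in PANC1, 2537 to 3027 in both, 1262 to 1850 for the difference and 11651 to 11985 between the control lines. With a 2-fold threshold the counts fell to 328, 372, 74, 187 and 5725 by construction. Without genes that carry the sites or lack a UTR, 3337 genes changed in MIA, 3529 in PANC1 and 1734 in both. These counts fall in part by construction, since fewer genes are left. Of the genes with a UTR tested in both lines, 25.3% carry AAAAGGA and 12.6% carry GACAGTA or GACGTA. Falls dropped more than rises: 1865 rose and 1472 fell in MIA (2712 and 2814 with all genes), 1998 and 1531 in PANC1 (2978 and 2837) and 978 and 756 in both (1450 and 1573).

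The number of lists that moved depends on the set test. With an estimated correlation it was 0 in MIA, 1 in PANC1, 0 for the difference and 0 between the control lines, against 4, 9, 3 and 8. Fry, which asks whether a set's genes move one way on balance and does not compare them with other genes, gave 17, 13, 6 and 24. The difference had 7 lists with a replicate block and 5 with log2(TPM + 1), and the cause was not tested. Leaving out 1 library gave 2 to 4 lists in MIA, 2 of them without control library 3 or siTCF7L1 library 3. In PANC1 it gave 6 to 9, with 6 lacking siTCF7L1 library 1, and between the control lines 8 to 9. For the difference it gave 3 to 8: 7 without MIA control library 1, 5 without MIA siTCF7L1 library 2 or PANC1 control library 3, and 6 and 8 without PANC1 siTCF7L1 libraries 1 and 2. Between the control lines fry's direction is opposite to the median for fibroblast markers (1.38) and leukocyte markers (−0.14), as a median and a signed test weigh members differently. Without genes that carry the sites 5 lists moved in MIA and 6 in PANC1. In MIA integrin and matrix genes then moved down (median −0.21 over 26 members, adjusted p = 0.0341; −0.12 over 32 with all genes). In PANC1 the small RNA, immediate early and oxidative phosphorylation calls were lost with medians of −0.24, −0.20 and 0.10, as with all genes, over 5, 21 and 33 members, and the cause was not tested. In MIA the small RNA median went from −0.23 to −0.02. The oxidative phosphorylation call is lost with a replicate block (adjusted p = 0.0590), fry (0.139) and without the sites (0.0794), with a median of 0.10 in each, the hypoxia call with fry (0.0632), and in MIA the ribosomal protein call with fry (0.115).

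Of the named genes, 10 lost a call under some alternative and 0 reversed. Among the differences, over 22 alternatives, TBC1D8B lost its call in 17, MAP1B in 5, TFPI2 in 4, HMGA2 in 3, MARCH4 and SLC35F3 in 2, and KANK1 and LRRC15 in 1. These genes had few reads in MIA, and the cause was not tested further. The replicate numbers do not pair the libraries: expression residuals of control and siTCF7L1 libraries of the same number correlated with r = 0.09, −0.07 and −0.04 in MIA and 0.03, −0.03 and −0.07 in PANC1, across genes, which are not independent replicates. With a replicate block, 5224 genes changed in MIA, 5288 in PANC1, 2744 in both, 1321 for the difference and 12074 between the control lines. At this depth 54% of simulated differences of 0.5 on the log2 scale were recovered, so small differences between the lines can be missed. The simulation changed 200 genes and 1775 passed in the data. The adjusted threshold was therefore stricter in the simulation, and its 54% need not hold for the data.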

Other observations

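The tests of a response to the loss of TCF7L1, of shorter forms of the sites in the transcript, of a longer match in LIN9 and ATN1 and of LIN9 acting alike in both lines were chosen only after the result was seen. Several stress and survival genes changed in both lines although their lists did not move. The p53 inhibitor MDM2 fell (−0.78 in MIA and −0.85 in PANC1), the polyamine enzyme SAT1 (1.03 and 0.76) and TP53INP1 (0.98 and 0.90) rose in both lines, and SESN2 rose in MIA (0.84) and did not pass in PANC1 (−0.16). Of 28 CDK inhibitor and p53 target genes measured in MIA, 11 rose, 8 fell and 9 did not pass (13 and 8 adjusted over the list alone), with a median of 0.17 and a camera adjusted p = 0.360. PANC1 had 28 measured, of which 6 rose, 7 fell and 15 did not pass (8 and 7 adjusted over the list alone), with a median of −0.00203 and a camera adjusted p = 0.796. Of the apoptosis regulators, the effector BAK1 rose (0.48 and 0.91) and the inhibitor BIRC2 (−0.69 and −0.85) and the BH3 gene PMAIP1 (−0.63 and −0.74) fell in both lines. In MIA, of 30 apoptosis regulators 11 rose, 5 fell and 14 did not pass (11 and 6 adjusted over the list alone), with a median of 0.05 and a camera adjusted p = 0.360. Among 28 in PANC1, 7 rose, 9 fell and 12 did not pass (7 and 9 adjusted over the list alone), with a median of −0.06 and a camera adjusted p = 0.643. The interferon-induced gene IFIT1 (−1.06 and −0.73) and SAMD9 (−1.11 and −0.81) fell in both lines and IFITM3 rose in PANC1 (0.42). The 35 interferon-stimulated genes of MIA did not move: 5 rose, 11 fell and 19 did not pass (6 and 11 adjusted over the list alone), with a median of −0.13 and a camera adjusted p = 0.289. Nor did the 35 of PANC1, where 9 rose, 4 fell and 22 did not pass (8 and 4 adjusted over the list alone), with a median of 0.01 and a camera adjusted p = 0.4998. Of the inflammatory genes, the NF-kappaB subunit NFKB2 rose in both lines (0.56 and 0.16), RELB (0.64) rose in MIA, and SOD2 (0.70) and the adhesion molecule ICAM1 (0.54) in PANC1. Of 18 NF-kappaB and inflammatory genes measured in MIA, 7 rose, 2 fell and 9 did not pass (7 and 2 adjusted over the list alone), with a median of 0.17 and a camera adjusted p = 0.253. PANC1 had 22 measured, of which 11 rose, 3 fell and 8 did not pass (11 and 3 adjusted over the list alone), with a median of 0.19 and a camera adjusted p = 0.0980.

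The amino acid transporter SLC7A5 (0.38 and 0.89) and PDIA4 (0.32 and 0.92) rose in both lines, and the chaperone CALR fell in MIA (−0.47). In MIA, of 30 unfolded protein and stress response genes 7 rose, 8 fell and 15 did not pass (7 and 9 adjusted over the list alone), with a median of 0.01 and a camera adjusted p = 0.942. Among 31 in PANC1, 8 rose, 8 fell and 15 did not pass (8 and 9 adjusted over the list alone), with a median of −0.14 and a camera adjusted p = 0.609. The mean of this list in MIA, −0.02, and camera's direction were negative and its median positive. Of the NRF2 targets, TKT rose in both lines (0.44 and 0.27) and SRXN1 fell in PANC1 (−0.80). The 25 NRF2 targets of MIA did not move: 7 rose, 5 fell and 13 did not pass (8 and 5 adjusted over the list alone), with a median of 0.02 and a camera adjusted p = 0.758. Nor did the 24 of PANC1, where 7 rose, 10 fell and 7 did not pass (7 and 10 adjusted over the list alone), with a median of −0.08 and a camera adjusted p = 0.4998. Their mean in MIA was −0.01, opposite in sign to the median and the test. The ribosome biogenesis genes NPM1 (−0.47 and −0.46), DDX21 (−0.43 and −0.49) and LYAR (−0.67 and −0.59) fell in both lines. Of 32 MYC and ribosome biogenesis genes measured in MIA, 5 rose, 8 fell and 19 did not pass (5 and 8 adjusted over the list alone), with a median of −0.02 and a camera adjusted p = 0.731. PANC1 had 32 measured, of which 1 rose, 11 fell and 20 did not pass (1 and 11 adjusted over the list alone), with a median of −0.04 and a camera adjusted p = 0.125. The linker histone HIST1H1C fell in MIA (−0.27) and had a value of −0.21 in PANC1, where it did not pass. In MIA, of 21 replication-dependent histone genes 0 rose, 2 fell and 19 did not pass (0 and 0 adjusted over the list alone), with a median of −0.18 and a camera adjusted p = 0.360. Among 18 in PANC1, 0 rose, 0 fell and 18 did not pass (0 and 0 adjusted over the list alone), with a median of −0.34 and a camera adjusted p = 0.230.

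The 1573 genes that fell in both lines include many with AAAAGGA in the 3′ UTR, as seed-matched off-target repression by the TCF7L1 siRNA could give. Of all 7-base sequences it went with the strongest fall in MIA (3121 genes, shift −0.11, t = −12.8) and ranked 1 in PANC1 (3360 genes, shift −0.13, t = −14.75), while 20 shuffles of the values reached t = −4.85 in MIA and −4.47 in PANC1, and it occurs in the TCF7L1 transcript, as 14.2% of such sequences do (coding sequence, chromosome 2 85306226 to 85306232, and 3′ UTR, 85309528 to 85309534, plus strand, GRCh38). Among genes without it, shared falls were 3.05 times the number for independent lists, and a ratio of at least 1.5 was to count against direct repression there. That bound took no account of shorter forms. Of the genes without AAAAGGA, 8048 had AAAAAG, AAAAGG, AAAGGA or AAGGAA in the longest transcript or the UTR, and 9.74% of these fell in both lines. The share was 2.56% among the 899 with none of these forms (longer transcripts carry more of them). Among those 899 genes, 23 fell in both lines, 4.54 times the number for independent lists (counting interval 2.88 to 6.82). This is beyond 1.5, but the ratio does not test direct repression through these forms, since the 899 genes were chosen for lacking them. Those 23 falls are free of the forms by that choice alone. The other 784 of the 807 shared falls without AAAAGGA carry a shorter form, so direct repression through such forms stays open for them. Among carriers of AAAAGGA the ratio was lower, 2.14, although 23.1% of them fell in both lines, against 9.02% of genes without it. The ratio has a lower ceiling where more genes are called, so it does not measure seed repression in general. LIN9 and ATN1 lack AAAAGGA, and a longer match to its sites is argued against for ATN1, as 78.1% of 12541 genes match at least as well at the coding site and 70.7% at the 3′ UTR site. It stays open for LIN9, with 6.475% at the coding site (15 of 21 bases) and 70.7% at the 3′ UTR site, and the sequence of the siRNA is not given in the sources used here. Whether the 807 shared falls without the sequence come from other sites, are a response to the loss of TCF7L1 or follow from off-target falls cannot be told apart, since the series holds 1 TCF7L1 siRNA.

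Among the 1450 genes that rose in both lines, GACAGTA or GACGTA was in the 3′ UTR of 20.9% of the 1408 with a UTR, against 12.6% of genes. GACAGTA went with the strongest rise in MIA (1074 genes, shift 0.07, t = 5.27) and ranked 1 in PANC1 (1158 genes, shift 0.13, t = 9.83), and it is absent from the TCF7L1 transcript. GACGTA was taken from other sequences with strong rises, such as TGACGTA and AGACGTA, so the shares of both among the rises follow in part from that choice. A loss of seed-matched repression by the control siRNA could give this pattern. Among genes without the sites, shared rises were 2.56 times the number for independent lists, beyond the bound of 1.5 set for this ratio. The ratio does not test direct relief, since these genes were chosen for lacking the sites. However, 79.1% of the 1408 lack both in the 3′ UTR. That share argues against direct relief through GACAGTA or GACGTA there as the cause of most rises. Among carriers the ratio was lower, 2.34, although 19.4% of them rose in both lines, against 10.6% of genes without the sites. For the same reason as in the falls, the ratio does not measure seed relief in general. The sequence of the control siRNA is not given in the sources used here, and relief through its other seeds was not tested. Shorter forms of the 2 sites change their result little: 11.0% of the 8905 genes with GACAGT, ACAGTA or GACGT in the longest transcript or the UTR rose in both lines, against 8.57% of the 1564 with none, where the ratio was 2.53 (95% counting interval 2.12 to 3.002). No biological explanation of the rises was tested, because the control siRNA is the only one in the series.

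The fall of G2/M and mitosis genes in PANC1 is not explained by AAAAGGA, GACAGTA or GACGTA in the 3′ UTRs of the list's own members, since the 42 members without them had a median of −0.44 (camera adjusted p = 3.38e-16). A trend with GC content and transcript length is argued against as well: a regression on both, which explains 6.42% of the variance, left the list median at −0.41, below all of 10000 random lists. LIN9 belongs to the MuvB complex, known to activate G2/M genes with B-MYB, and its fall might lower them, but LIN9's difference between the lines was −0.04 ± 0.16 (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.923) while the list's median difference was −0.33. This argues against a fall of LIN9 acting with equal strength in both lines, with the reserve that the list's difference has an adjusted p = 0.210 with an estimated correlation. A response to the loss of TCF7L1 and a line-dependent effect of LIN9 stay open, as untested. So do direct repression through shorter forms of AAAAGGA, for which the 42 members were not screened, and indirect effects of off-target falls.

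The 6 libraries of each 2-group comparison allow 10 splits, too few for a share under 0.05. The real split gave 5526 genes in MIA, 5815 in PANC1 and 12070 between the control lines, 1 of the 10 in each, and the highest of the others gave 0. For the 3023 genes changed the same way in both lines, 1 of 100 splits, the real one, gave as many and the highest other gave 161. This share argues against a chance division of the libraries in both lines at once. Splits that mixed the arms of a line gave 0 calls in that line, so this share follows from the calls within the lines and does not test the sharing itself.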
